A study of Sus scrofa with 5 samples.

How the data were processed

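Porcine total RNA was measured on Affymetrix 3' expression arrays, 1 array per sample. The 5 samples fall into 2 groups by their labels. One group held 3 clones of induced porcine pluripotent stem cells (iPPSC), named IC1, ID4 and ID6 and harvested at passage 7 after 5 days on irradiated mouse embryonic fibroblast feeder cells. Per the labels, these clones came from fetal fibroblasts that had received human OCT4, SOX2, KLF4 and c-MYC by lentivirus. The other group held 2 arrays of the progenitor cells, porcine fetal fibroblasts carrying enhanced green fluorescent protein (PFF), derived at day 34 of pregnancy and grown in DMEM with 10% fetal bovine serum. The clones were grown in a medium for human embryonic stem cells with 4 ng/ml human FGF2, so medium and feeder differ between the groups together with cell state. The labels call the PFF arrays biological replicates and do not say whether they are separate cultures or separate fetuses. For this reason, and because the clones share a fibroblast origin, p-values measure only the spread between these samples.

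The deposited values are a signal intensity per probe set on a linear scale, as read from the values themselves. Per the labels' protocols, 10 µg of total RNA was labelled with biotin by a 3' in vitro transcription kit. In the deposited values each array's mean, trimmed of 2% at each end, was 500, the value that scaling every array to a shared target would leave; no source used here records that step. The summarisation algorithm, its software and the array's genome build are not given in the sources used here, and no detection calls were used. No coordinates are printed for this reason.

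The array held 24123 probe sets. After 124 control probe sets were left out, 23999 were tested. Gene symbols came from the platform annotation of August 2016 and were updated through gene identifiers to the reference gene table of assembly Sscrofa11.1, in which 9989 probe sets found their identifier. A single symbol was given to 10069 probe sets, several symbols to 198 and none to 13732, which are unnamed here. The 6765 genes so named were each represented by the probe set with the highest mean over the 5 arrays. Of the 2261 genes with several probe sets, 96 had probe sets that passed the test in both directions. NANOG, SOX2, LIN28A, SALL4, TDGF1, DPPA4 and COL1A1 have no probe set with a symbol here and were not analysed. List members that the annotation holds under an older symbol were matched by hand.

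Values were transformed as log2(signal + 16) without further normalisation. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 23999 probe sets and a threshold of 0.05 on the adjusted p. Log2 differences are iPPSC minus PFF on the log2(signal + 16) scale, given with their standard error (SE), and understate the change of dim genes. Signals are given as mean ± SD over 3 iPPSC and 2 PFF arrays. The highest of 59 negative-control probe sets ranged from 15.3 to 23.0 per array. Where every array of a group lay at or below that level, only a bound is given: the brighter group's mean log2 signal against, per array, the higher of the negative-control level and the probe set's own signal, written as at least N-fold.

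The genes named were chosen by a rule: the 10 genes with the largest positive and the 10 with the largest negative difference that passed the test with all clones beyond both PFF arrays; the introduced factors and a fixed set of pluripotency, epithelial and fibroblast genes whatever their value; in each gene list up to 3 members per direction that passed the test; and for each clone the 5 genes with the widest gap to the nearer of the other clones, above the median mean expression. The shift of 31 gene lists, 7 of them primary, was tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over all lists. Camera with an estimated correlation and fry were run beside it. Each clone is a single array, so no test between clones was made. For each list, a clone's median difference from the mean of the other clones was ranked among 10000 random lists of matched size and mean expression. The alternatives tried were quantile normalisation, median centring, filters on dim probe sets, other prior variances, offsets of 1 and 64, a threshold of 0.01, the mean of all probe sets of a gene, and leaving out each array in turn.

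The method was tested on simulated data for iPPSC against PFF with 23999 probe sets. It recovered 40% of 100 simulated changes of 1 on the log2 scale and 79% of 100 changes of 2, with 3 false calls. It called 0 probe sets where no change was simulated. Far fewer probe sets were changed than the 53.3% called in the data, and noise was drawn independently for each probe set. These rates therefore do not carry over to the comparison reported here. The number of arrays limits the precision.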

Results

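Gene expression was measured in 3 clones of induced pluripotent stem cells and in 2 arrays of the fetal fibroblasts they were made from, all from pig. The median signal ranged from 97.1 to 102 on the iPPSC arrays and was 111 and 118 on the PFF arrays. Between 71.5% and 76.8% of probe sets lay above the array's highest negative control. Across probe sets the clones correlated with each other at r between 0.985 and 0.991, the PFF arrays with each other at 0.991, and clones with PFF arrays at 0.840 to 0.847. Probe sets are not independent replicates. The arrays' own actin control differed between the groups: its 3' to 5' signal ratio was 6.62 ± 0.38 (SD, n = 3) in iPPSC and 1.87 ± 0.16 (SD, n = 2) in PFF. The same ratio for the GAPDH control was 1.23 ± 0.01 (SD, n = 3) in iPPSC and 1.23 ± 0.07 (SD, n = 2) in PFF. Every comparison between the groups below was made on these same arrays.

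The first comparison asked how the clones differ from their progenitor fibroblasts. Epithelial genes made up much of the largest rises. The keratin KRT18 had a signal of 5207 ± 1578 (SD, n = 3) in iPPSC and 3.03 ± 0.66 (SD, n = 2) in PFF, at least 220-fold higher (adjusted p = 2.44e-05). CDH1, the E-cadherin of adherens junctions, was at least 223-fold higher (5218 ± 1297 against 22.1 ± 1.2, adjusted p = 2.31e-05). EPCAM, an epithelial adhesion molecule, was at least 134-fold higher (3536 ± 2393 against 12.8 ± 2.2, adjusted p = 0.000223), and LSR, a tricellular junction receptor, at least 84.7-fold higher. KRT8, the partner of KRT18 in filaments, rose by 5.19 (SE 0.16) on the log2 scale, and the desmosomal plaque protein DSP by 5.66 (SE 0.13). KRT19 rose by 6.02 (SE 0.32), with 1 of the PFF arrays within the negative controls.

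Of the 28 measured genes of epithelial junctions and keratins, 19 rose, 2 fell and 7 did not pass the test, and 19 and 2 did when adjusted over the list alone. The list's median was 2.27 and its shift passed camera's test (adjusted p = 0.000199), but not with an estimated correlation (adjusted p = 0.423 with an estimated correlation). One of the genes counted as having risen, EHF, an epithelial transcription factor chosen after its values were seen, lay within the negative controls on all arrays. The members that fell were JUP, which encodes plakoglobin, by 1.61 (SE 0.17), and CDS1, a phospholipid synthesis enzyme, by 1.41 (SE 0.15). Other genes among the 10 largest rises were FABP7, a fatty acid binding protein of neural progenitors, at 7.56 (SE 0.15), the retinoic acid hydroxylase CYP26A1 at 6.29 (SE 0.59), the apolipoprotein APOE at 5.70 (SE 0.38) and the tetraspanin TSPAN13 at 5.59 (SE 0.13). The difference of APOE was 6.36 without PFF replicate 1 and 5.05 without PFF replicate 2, and that of CYP26A1 was 6.89 without clone ID6.

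**Figure D1:**
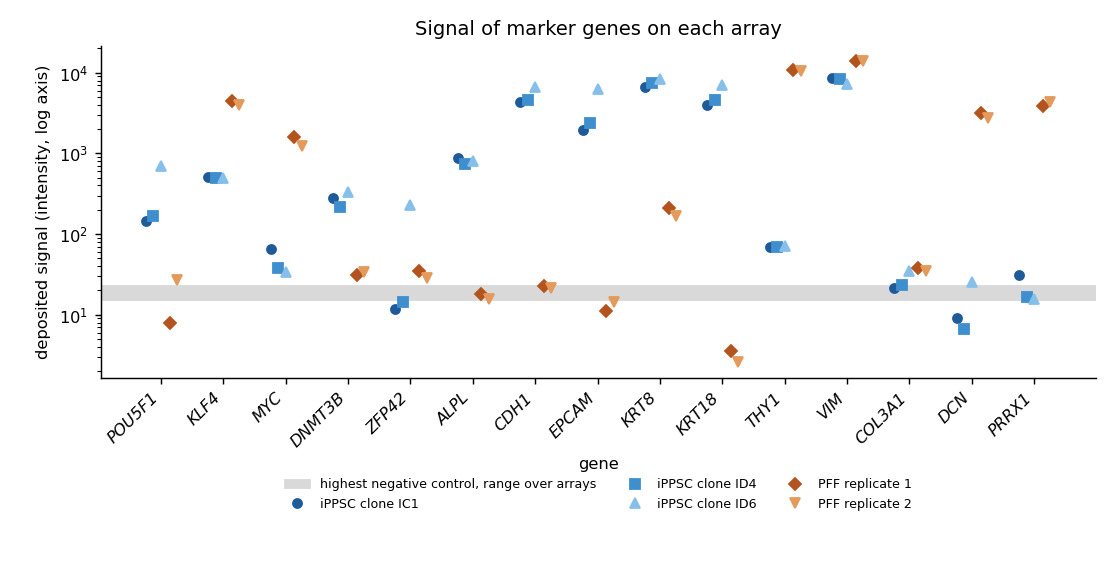
Deposited signal (intensity, log axis) of 15 marker genes on each array; blue symbols are the 3 iPPSC clones, orange symbols the 2 PFF arrays, and the grey band is the range over arrays of the highest negative control. KRT18 averaged 5207 in iPPSC and 3.03 in PFF, while THY1 averaged 69.9 and 10560.

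Of the 10 genes with the largest falls, 5 belonged to the extracellular matrix list. ASPN, a small proteoglycan, had a signal of 10.4 ± 2.2 (SD, n = 3) in iPPSC and 12390 ± 758 (SD, n = 2) in PFF, at least 673-fold lower (adjusted p = 9.02e-06). MGP, the matrix Gla protein, was at least 520-fold lower (7.81 ± 2.88 against 9570 ± 142), the bone and matrix phosphoprotein SPP1 at least 422-fold lower, and the collagen gene COL8A1 at least 253-fold lower. Thrombospondin 2 (THBS2) fell by 7.58 (SE 0.12) on the log2 scale, and the collagen gene COL15A1 fell by 7.49 (SE 0.21). AEBP1, a collagen-binding protein, fell by 7.68 (SE 0.35), and the muscle intermediate filament gene DES fell by 7.41 (SE 0.12). THBS2 and AEBP1 each lay above the negative controls in only 1 of the 3 clones, so the sizes of their falls are uncertain. PALMD was at least 166-fold lower and the mitochondrial sulfide oxidase gene SQOR at least 158-fold lower.

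Of 43 measured extracellular matrix genes 40 fell, 1 rose and 2 did not pass the test, with 40 and 1 adjusted over the list alone. The median was -3.94 (camera adjusted p = 1.28e-14; adjusted p = 0.224 with an estimated correlation). FBLN1, a basement membrane fibulin, was the gene that rose, by 2.53 (SE 0.25). COL3A1, a fibrillar collagen, had a difference of -0.30 (SE 0.17, adjusted p = 0.187), with signals of 26.7 ± 7.5 in iPPSC and 36.2 ± 2.1 in PFF. Without clone ID6 its difference was -0.44 and passed the test (adjusted p = 0.0266). Its single probe set was dim in both groups and lay above the negative controls in only 2 of the 3 clones. The size of the COL3A1 difference is therefore uncertain in both fits.

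Genes of mesenchymal and fibroblast identity fell in 17 of 22 cases, with 1 that rose and 4 that did not pass, and 17 and 1 adjusted over the list alone. The median was -2.39 (camera adjusted p = 1.98e-05; adjusted p = 0.224 with an estimated correlation). The surface antigen THY1 fell by 6.94 (SE 0.10), from 10560 ± 291 (SD, n = 2) to 69.9 ± 0.55 (SD, n = 3), and the homeobox gene PRRX1 fell by 6.82 (SE 0.20). Decorin (DCN) fell by 6.70 (SE 0.28), with only 1 of the 3 clones above the negative controls. VIM, which encodes the intermediate filament vimentin, fell by 0.81 (SE 0.12), with signals of 8034 ± 716 in iPPSC and 14010 ± 43.6 in PFF. Whether signals this bright are compressed by saturation was not tested. PDPN, a membrane glycoprotein of several epithelia and stromal cells, rose by 1.61 (SE 0.21). Without clone ID4, and also without PFF replicate 2, 2 genes of this list rose. The clones were grown on mouse fibroblasts, and whether these probe sets also bind mouse transcripts is not known.

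Contractile and actin cytoskeleton genes fell in 25 of 27 cases, 0 rose and 2 did not pass, with 25 adjusted over the list alone. The median was -1.96 (camera adjusted p = 2.29e-09; adjusted p = 0.423 with an estimated correlation). Calponin 1 (CNN1) fell by 5.63 (SE 0.25), the tropomyosin gene TPM2 fell by 4.61 (SE 0.18) and the actin-associated PDLIM7 fell by 3.88 (SE 0.21). On these arrays the 5' actin control gave 1709 ± 53.7 in iPPSC and 5755 ± 254 in PFF, and the 3' actin control 11299 ± 338 and 10733 ± 453.

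Of the 4 introduced factors 3 were measured. POU5F1, the gene of OCT4, rose by 3.11 (SE 0.71, adjusted p = 0.0135), with signals of 143, 170 and 702 in clones IC1, ID4 and ID6 and of 7.94 and 26.8 in PFF. Without PFF replicate 1 its adjusted p was 0.0903, the highest of a range over all alternatives that began at 0.0037, and without clone ID6 its difference was 2.43. KLF4 fell by 3.04 (SE 0.11), from 4199 ± 328 (SD, n = 2) in PFF to 497 ± 8.99 (SD, n = 3) in iPPSC. MYC fell by 4.54 (SE 0.25), from 1402 ± 249 to 45.8 ± 17.3. Taken as a list, 1 rose, 2 fell and 0 did not pass, 1 and 2 adjusted over the list alone, and the shift did not pass camera's test (median -3.04, adjusted p = 0.231). The probe sequences were not used here, so whether these probe sets also bind the introduced human transcripts is not known.

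Of 58 genes listed for the pluripotency network only 16 were measured, without NANOG, LIN28A, SALL4, TDGF1 and DPPA4. Of these 16 genes 11 rose, 2 fell and 3 did not pass, with 11 and 2 adjusted over the list alone. ALPL, the tissue-nonspecific alkaline phosphatase, was at least 34.9-fold higher (804 ± 68.2 against 17.0 ± 1.7, adjusted p = 1.83e-05). The kinase gene PIM2 rose by 3.32 (SE 0.14), the de novo DNA methyltransferase gene DNMT3B by 2.58 (SE 0.19), and the nuclear receptor gene NR0B1 was at least 4.83-fold higher. STAT3, the transducer of LIF signalling, fell by 3.46 (SE 0.20) and the gap junction gene GJA1 fell by 3.01 (SE 0.18). ZFP42, the gene of REX1, had a difference of 0.31 (SE 0.99, adjusted p = 0.824), with signals of 11.7, 14.4 and 229 in clones IC1, ID4 and ID6 and of 35.3 and 28.5 in PFF. The list's median was 1.55 (camera adjusted p = 0.0283; adjusted p = 0.423 with an estimated correlation). Without clone ID6 its adjusted p was 0.0518, with median centring 0.0565 and with only probe sets above the 40th percentile of expression 0.0519. Without clone ID6 the ZFP42 signal was lower in iPPSC (adjusted p = 0.0105), but both remaining clones lay within the negative controls, so no size is given.

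Genes of cell division rose. All 28 measured DNA replication genes rose, 28 adjusted over the list alone, with a median of 1.60 (camera adjusted p = 2.29e-09; adjusted p = 0.224 with an estimated correlation). The largest rises were of the origin recognition gene ORC1 at 2.96 (SE 0.11), the polymerase epsilon subunit gene POLE2 at 2.88 (SE 0.20) and the helicase gene MCM2 at 2.76 (SE 0.10). Of 27 mitosis genes 24 rose, 0 fell and 3 did not pass, 24 adjusted over the list alone, with a median of 1.42 (camera adjusted p = 1.79e-07; adjusted p = 0.224 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, rose by 2.81 (SE 0.13), the mitotic kinase gene PLK1 by 2.35 (SE 0.10) and securin (PTTG1) by 2.28 (SE 0.17). Of 24 genes of DNA methylation and chromatin 21 rose, 0 fell and 3 did not pass, 21 adjusted over the list alone, with a median of 1.13 (camera adjusted p = 3.33e-06; adjusted p = 0.224 with an estimated correlation). The architectural protein gene HMGA1 rose by 3.69 (SE 0.11), the remodeller gene CHD7 by 3.48 (SE 0.13) and the histone methyltransferase gene EHMT2 by 2.15 (SE 0.13).

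All 32 measured genes of ribosome biogenesis and MYC targets rose, 32 adjusted over the list alone, with a median of 1.56 (camera adjusted p = 1.76e-09; adjusted p = 0.355 with an estimated correlation). Among them PPAN rose by 2.54 (SE 0.12), the nucleostemin gene GNL3 by 2.39 (SE 0.10) and WDR12 by 2.36 (SE 0.13). Of 31 oxidative phosphorylation genes 25 rose, 1 fell and 5 did not pass, 25 and 1 adjusted over the list alone, with a median of 0.73 (camera adjusted p = 5.69e-05; adjusted p = 0.457 with an estimated correlation). The complex I gene NDUFS1 rose by 1.24 (SE 0.10) and the complex II gene SDHB by 1.22 (SE 0.10). The gene that fell was the ATP synthase gene ATP5J, by 0.61 (SE 0.10); with the mean of its probe sets its adjusted p was 0.245.

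Of 44 cytosolic ribosomal protein genes 19 rose, 1 fell and 24 did not pass, 17 and 1 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.000643; adjusted p = 0.580 with an estimated correlation). RPL30 rose by 2.15 (SE 0.16) and RPL37 fell by 1.07 (SE 0.14). The number of ribosomal protein genes that rose was 4 without PFF replicate 1 and also without PFF replicate 2, 7 without clone ID4 and 10 without clone ID6; it was 10 with quantile normalisation, 31 with an offset of 64, 39 with a trend in the prior variance and 40 with median centring. In serine, one-carbon and nucleotide synthesis 14 of 23 genes rose, 5 fell and 4 did not pass, 14 and 5 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 0.0134; adjusted p = 0.423 with an estimated correlation). TDH, the threonine dehydrogenase, was at least 41.1-fold higher, and PPAT, the first enzyme of de novo purine synthesis, rose by 5.13 (SE 0.16). The glycine cleavage gene AMT rose by 4.45 (SE 0.21). The genes of the serine synthesis pathway fell: PSAT1 by 2.16 (SE 0.41), PSPH by 1.09 (SE 0.16) and PHGDH by 0.98 (SE 0.22). PHGDH did not pass without PFF replicate 1 (adjusted p = 0.0712) or PFF replicate 2 (adjusted p = 0.071), and the number of genes of this list that fell was then 2 and 3.

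**Figure D2:**
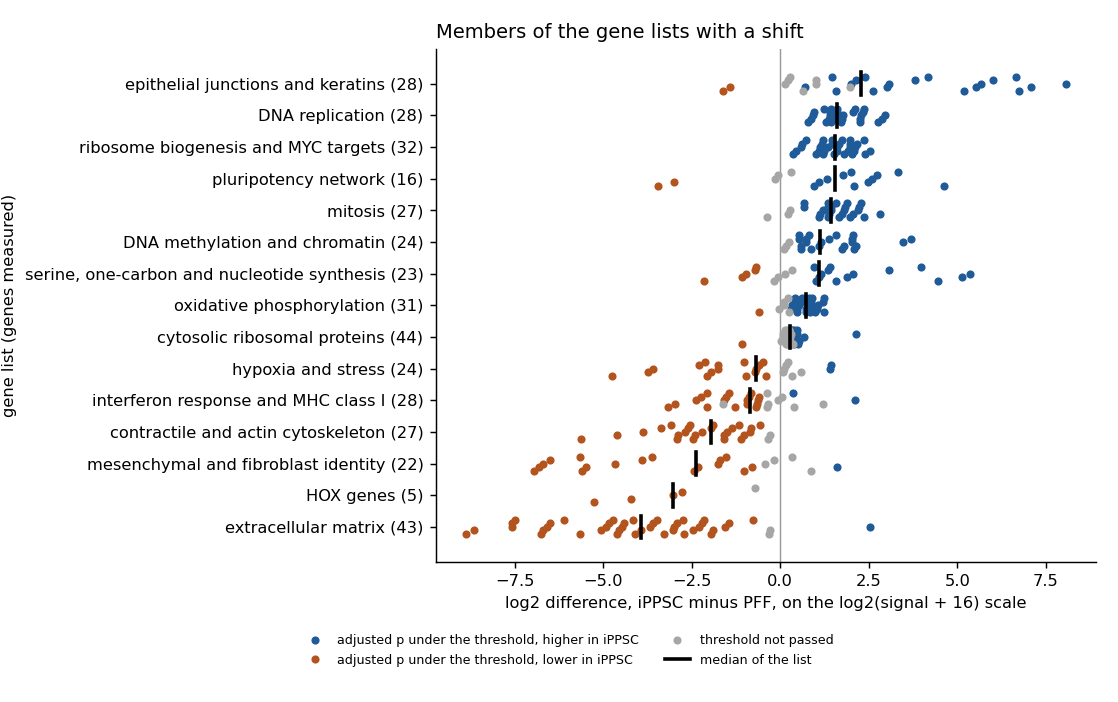
Log2 differences (iPPSC minus PFF, on the log2(signal + 16) scale) of the members of the 15 gene lists whose shift passed camera's test; each point is a gene, blue for genes that rose, orange for genes that fell and grey for those that did not pass, and black bars are list medians. All 28 DNA replication genes lie above 0, and 40 of 43 extracellular matrix genes fell.

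Several lists besides those of fibroblast identity fell. Only 5 of 35 listed HOX genes were measured. Of these 4 fell, 0 rose and 1 did not pass, 4 adjusted over the list alone, with a median of -3.02 (camera adjusted p = 0.00738; adjusted p = 0.387 with an estimated correlation). HOXA9, a patterning gene of the posterior body axis, was at least 35.5-fold lower, HOXA3 at least 21.4-fold lower and HOXB7 at least 11.2-fold lower. With these genes placed at their bounds the list's median was -3.49. With only probe sets above the 40th percentile of expression the list did not pass (adjusted p = 0.0863).

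Of 28 genes of the interferon response and MHC class I 18 fell, 2 rose and 8 did not pass, with 19 and 2 adjusted over the list alone, and the median was -0.84 (camera adjusted p = 0.00191; adjusted p = 0.423 with an estimated correlation). The class I genes SLA-2 and SLA-3 fell by 3.18 (SE 0.28) and by 2.98 (SE 0.22), and the interferon-induced IFIT3 fell by 2.37 (SE 0.16). The kinase gene EIF2AK2 rose by 2.10 (SE 0.29). B2M, the light chain of class I molecules, rose by 0.36 (SE 0.11, adjusted p = 0.0347) on its brightest probe set. Of its 9 probe sets 5 passed in the opposite direction, and the mean of all 9 fell by 0.55. Without PFF replicate 1 the adjusted p of its brightest probe set was 0.146, without PFF replicate 2 0.0878, without clone ID4 0.107 and without clone ID6 0.0626, which left 1 gene of the list that rose in each of these except without PFF replicate 2.

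Of 24 hypoxia and stress genes 16 fell, 2 rose and 6 did not pass, 16 and 3 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.00609; adjusted p = 0.224 with an estimated correlation). Adrenomedullin (ADM) fell by 4.74 (SE 0.18), the stress transcription factor gene DDIT3 fell by 3.74 (SE 0.20) and the angiogenic factor VEGFA fell by 3.59 (SE 0.15), with 1 of its 4 probe sets passing in the opposite direction. The carbonic anhydrase gene CA9 rose by 1.44 (SE 0.16) and the glutathione synthesis gene GCLM by 1.42 (SE 0.20).

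Over all 23999 probe sets, 6439 were higher and 6351 lower in iPPSC, 53.3% of those tested, and 3446 were at least 2-fold higher and 3832 at least 2-fold lower. Among genes with a symbol, 2283 were higher and 1969 lower. Centring each array on its median moved the median difference over all probe sets from 0.005 to 0.195 and the share of higher among the at least 2-fold calls from 47.4% to 57.5%, with 4312 higher and 3186 lower. Medium, feeder and cell state differed together between the groups and cannot be separated on these arrays. No list passed with an estimated correlation, the lowest adjusted p being 0.224. That version of camera had little power here, with 3 residual degrees of freedom. For the mesenchymal list the estimated correlation was -0.0015, below the preset 0.01. Its unadjusted camera p still went from 4.47e-06 with the preset to 0.015 with the estimate. A failure with an estimated correlation therefore does not show that correlation between genes accounts for a shift.

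The second comparison asked how far the clones differ from each other. Clone ID6 stood further from the others: 763 probe sets were at least 2-fold apart between IC1 and ID6 and 589 between ID4 and ID6, against 296 between IC1 and ID4 and 327 between the PFF arrays. At least 2-fold higher than in both other clones were 213 probe sets in ID6, 29 in IC1 and 40 in ID4, and at least 2-fold lower were 94, 70 and 33. In ID6 the neuronal tubulin regulator STMN2 had a signal of 704, against 6435 in IC1, 5990 in ID4 and a mean of 2776 in PFF. The ubiquitin-like interferon-induced ISG15 had 629 in ID6 against 84.1 and 82.6, the protease inhibitor SPINT2 1008 against 81.3 and 170, and the claudin CLDN7 1261 against 194 and 271. In PFF these averaged 227, 52.6 and 34.3. An uncharacterised locus, LOC100621607, had 125 in ID6 against 1868 and 990, and 604 in PFF.

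Genes of epithelial junctions and keratins had a median 0.80 higher on the log2 scale in ID6 than the mean of the other clones, a percentile of 100 among 10000 random lists, with 23 of 28 members above both. The contractile list had a median of -0.23 in ID6 (percentile 0), with 23 of 27 members below both other clones. The interferon and MHC class I list had a median of 0.26 in ID6 (percentile 99.3), with 19 of 28 members above both, and the trophoblast list a median of 0.43 (percentile 99.9), with 13 of 19 above both. In IC1, 41 of 44 ribosomal protein genes lay below both other clones, with a median of -0.09 (percentile 0.05). Random lists hold unrelated genes while the members of these lists vary together, so a shift of 1 array can give an extreme percentile, which describes these arrays and is no test. These 5 were picked from 31 lists in each of 3 clones after their values were seen.

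In IC1, HTATIP2, an oxidoreductase and cell-death gene, had a signal of 11.5, within the negative controls, against 523 in ID4, 1220 in ID6 and 361 in PFF. P14ARF, the annotation's name for a product of the CDKN2A locus, had 79.0 in IC1 against 334 and 668, and 111 in PFF. The hyaluronan link protein gene HAPLN1 had 106 against 280 and 321, the prostaglandin E synthase gene PTGES 50.8 against 139 and 340, and the uncharacterised LOC100523870 102 against 341 and 312. In PFF these averaged 147, 586 and 7922. In ID4, the imprinted gene NDN, which encodes necdin, had 338 against 1.62 in IC1 and 3.00 in ID6, both within the negative controls, and 1523 in PFF. The proteoglycan gene BGN had 16.1 in ID4 against 144 and 59.4, ANKRD37 had 108 against 253 and 242, and the ubiquitin-binding PLAA 456 against 958 and 839. Their means in PFF were 7923, 121 and 466. AEBP1 had 23.6 in ID4 against 2.40 and 4.36, close to the negative controls in all clones. Each clone is a single array, so these gaps have no replicate check.

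**Figure D3:**
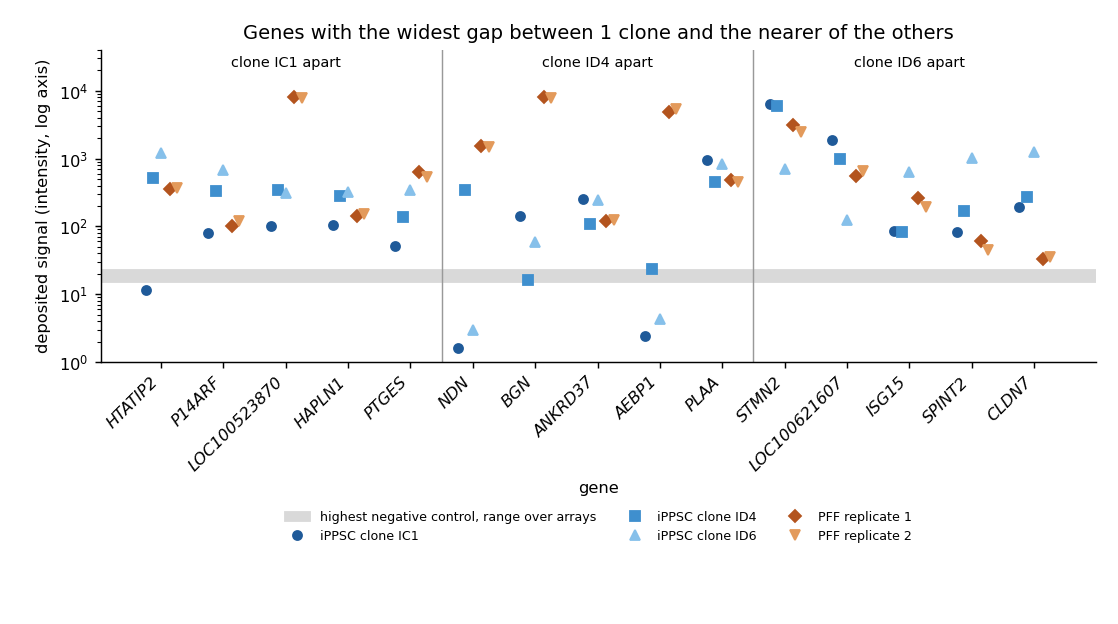
Deposited signal (intensity, log axis) on each array of the 5 genes per clone with the widest gap to the nearer of the other clones; blue symbols are clones, orange symbols PFF arrays, and the grey band is the range over arrays of the highest negative control. NDN lies at 338 in clone ID4 and at 1.62 and 3.00 in the other clones.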

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

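One filter, which kept only probe sets above the highest negative control on every array of at least 1 group, was added after the data were seen. The other alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Over all alternatives the probe sets higher and lower in iPPSC stayed within 1.5 times the counts reported, from 4795 to 7969 higher and from 4825 to 6439 lower. Leaving out each array in turn gave 5060 to 6315 higher and 5091 to 6424 lower; a group left with 1 array was assumed to vary like the other. No paired analysis was possible because the clones' labels carry no replicate numbers that PFF could share. Among the primary lists, the pluripotency network lost its call with median centring (median 1.74), above the 40th percentile of expression (2.00), at a threshold of 0.01 (1.55) and without clone ID6; its medians ranged from 1.48 to 1.59 over the arrays left out. Its adjusted p ranged from 0.00236 with fry to 0.423 with an estimated correlation. With an estimated correlation the shifts of the pluripotency (1.55), epithelial (2.27), mesenchymal (-2.39), matrix (-3.94), mitosis (1.42) and replication (1.60) lists no longer passed, and with fry that of the introduced factors (-3.04) did (adjusted p = 0.00013). Fry, which does not compare a list with other genes, passed 27 of 31 lists. Above the 40th percentile the pairs IC1 to ID4, IC1 to ID6, ID4 to ID6 and the PFF arrays had 63, 392, 245 and 83 probe sets at least 2-fold apart, and 40, 171, 97 and 25 were at least 3-fold apart; fewer probe sets and a wider gap account for the lower counts by construction. Without an array, ZFP42 ranged from -0.72 (without clone ID6, a changed direction with both remaining clones within the negative controls, so that its size was not measured) to 0.85; B2M changed direction with the mean of its probe sets (-0.55); the cause was not tested. Of 2538 values of 171 named genes under the alternatives, 2449 kept their side of the threshold, 73 no longer passed, 14 newly passed and 2 reversed. A changed sign counted as a reversal only where the gene passed in the main fit or the alternative. Without clone IC1, HTATIP2 went from -0.515 to 1.115 and LOC100621607 from 0.062 to -0.712. Neither passed, so both are counted among the 2449. Dim genes are limited by the negative controls, and placing members at their bounds moved the medians of lists that passed by at most 0.46.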

Other observations

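The tests of RNA degradation, signal saturation, human transcripts and chromosome number were chosen after the result was seen. Those of array scaling, dilution, position along the fibroblast to iPPSC difference and serum were written down before their own values were seen. They concern patterns found in these same data, the distance of clone ID6 and the lower KLF4 and MYC signals. Lists whose shift did not pass camera's test held single genes with wide differences. The activin antagonist FST rose by 4.29 (SE 0.22) and the ligand gene TGFB3 was at least 105-fold lower, among 25 genes of TGF-beta, activin and BMP signalling of which 4 rose, 11 fell and 10 did not pass, 5 and 12 adjusted over the list alone (camera adjusted p = 0.094, and 0.0367 with only probe sets above the 40th percentile of expression). The WNT receptor gene FZD5 rose by 3.93 (SE 0.16) and DKK3 fell by 5.63 (SE 0.13), among 14 WNT genes of which 5 rose, 4 fell and 5 did not pass, 5 and 4 adjusted over the list alone (adjusted p = 0.978; median 0.19, mean -0.01). FGFR1 rose by 1.28 (SE 0.18) and JUN fell by 3.69 (SE 0.28), among 18 FGF and MAPK genes of which 4 rose, 8 fell and 6 did not pass, 4 and 8 adjusted over the list alone (adjusted p = 0.322). The cell cycle inhibitor gene CDKN1B fell by 3.20 (SE 0.13), among 23 genes of p53 and growth arrest of which 4 rose, 13 fell and 6 did not pass, 4 and 13 adjusted over the list alone (adjusted p = 0.094).

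The glucose transporter genes moved apart, SLC2A3 rising by 3.19 (SE 0.20) while SLC2A1 fell by 0.72 (SE 0.12), among 17 glycolysis genes of which 6 rose, 1 fell and 10 did not pass, 5 and 1 adjusted over the list alone (adjusted p = 0.207); without clone ID6 2 fell. Of 15 cholesterol synthesis genes 3 rose, 5 fell and 7 did not pass, 3 and 5 adjusted over the list alone (adjusted p = 0.678); ACAT2 rose by 2.15 (SE 0.10). Of 19 imprinted genes 3 rose, 7 fell and 9 did not pass, 3 and 7 adjusted over the list alone (adjusted p = 0.171). PHLDA2, a brake on placental growth, fell by 4.76 (SE 0.15), and PEG3 was at least 8.18-fold lower. NDN fell by 4.97 (SE 1.37). Its difference was -4.23 without clone IC1 (adjusted p = 0.0685), -4.28 without clone ID6 (0.0697), -4.94 without PFF replicate 1 (0.117) and -4.995 without PFF replicate 2 (0.113). Without clone ID4 the fall of NDN passed (adjusted p = 0.00027), with both remaining clones within the negative controls, so that its size there is not given.

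The lists of markers of other cell types did not pass camera's test. Of 18 early endoderm genes 6 rose, 5 fell and 7 did not pass, 6 and 5 adjusted over the list alone (adjusted p = 0.987), with a median of -0.09, a mean of 0.57 and a median of 0.39 with dim members at their bounds; FOXA1 was at least 11.1-fold higher, CXCR4 rose by 4.41 (SE 0.42) and DAB2 fell by 4.88 (SE 0.27). Over the 11 endoderm genes above the negative controls in at least 1 group the median was 1.19, with 6 that rose and 4 that fell. Over the 7 above the 40th percentile of expression it was 2.58, with 4 that rose and 2 that fell. The list passed camera's test in neither setting. Of the endoderm genes that fell, PDX1, chosen after its values were seen, lay within the negative controls on all arrays. Of 19 trophoblast genes 3 rose, 3 fell and 13 did not pass, 3 and 2 adjusted over the list alone (adjusted p = 0.912), and TFAP2C was at least 17.1-fold higher; without clone IC1 5 rose. Of 12 neural genes 4 rose, 2 fell and 6 did not pass, 5 and 2 adjusted over the list alone (adjusted p = 0.565). Of 11 genes of early mesoderm and heart 1 rose, 6 fell and 4 did not pass, 1 and 6 adjusted over the list alone (adjusted p = 0.171); 0 rose and 4 fell without PFF replicate 1 and also without PFF replicate 2. Of 10 germ line genes 1 rose, 2 fell and 7 did not pass, 1 and 2 adjusted over the list alone (adjusted p = 0.328). Of 18 skeletal muscle genes 4 rose, 6 fell and 8 did not pass, 4 and 6 adjusted over the list alone (adjusted p = 0.207), and the acetylcholine receptor gene CHRNA1 fell by 5.33 (SE 0.14); 2 rose without PFF replicate 1 and also without PFF replicate 2. Of 15 endothelial genes 3 rose, 6 fell and 6 did not pass, 3 and 6 adjusted over the list alone (adjusted p = 0.394), and ERG fell by 4.07 (SE 0.28); 1 rose and 4 fell without PFF replicate 1 and also without PFF replicate 2. ERG lay above the negative controls in only 1 of the 3 clones, so the size of its fall is uncertain. Of the endothelial genes that rose, TIE1 lay within the negative controls on all arrays and CDH5 above them on 1. Of 11 endothelial genes above the negative controls in at least 1 group, 1 rose and 6 fell. Of 27 blood and immune genes 5 rose, 2 fell and 20 did not pass, 5 and 1 adjusted over the list alone (adjusted p = 0.870), with a median of -0.03 and a mean of 0.27; beta-globin (HBB) rose by 2.48 (SE 0.19) and AIF1 was at least 16.6-fold higher. Without clone ID4, PFF replicate 1 or PFF replicate 2 in turn, 1 of these fell. Of the 27 blood and immune genes, 15 had only a bound or no fold. Over the 10 above the negative controls in at least 1 group the median was 0.53, with 6 that rose and 1 that fell. Median centring raised all genes alike and so turned the small negative medians of the cholesterol, endoderm, trophoblast and blood lists positive by construction.

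Clone ID6 lay further from IC1 and ID4 than these lay from each other. After quantile normalisation its counts of probe sets at least 2-fold apart were still 1.82 and 2.31 times the IC1 to ID4 count, which argues against array scaling. Dilution by fibroblast RNA would lower the genes typical of iPPSC. Over 975 probe sets at least 4-fold higher in iPPSC, ID6 differed from the mean of the others by a median of 0.043. That gives no sign of a large share of fibroblast RNA. A small share is not excluded, and the probe sets were chosen on a mean that includes ID6. Dilution by feeder RNA cannot be judged this way. The trimmed means of all arrays were alike, and such scaling would hide RNA that binds no probe set. A position further along the fibroblast to iPPSC difference would raise one side and lower the other. ID6 minus IC1 had a median of 0.03 over probe sets at least 4-fold higher in ID4 than PFF. Over those at least 4-fold lower the median was 0.04. Genes such as ASPN and MGP lay within the negative controls in all clones and could hardly fall further. With 1 array per clone, these medians argue only against a shift of the whole profile. In ID6 the epithelial (0.80), pluripotency (0.24), contractile (-0.23), matrix (-0.12) and mesenchymal (-0.11) lists did lie that way from the mean of the others. So did, by less, the serine (0.09), ribosome biogenesis (0.08), ribosomal protein (0.035) and oxidative phosphorylation (0.03) lists. The interferon and MHC class I (0.26) and HOX (0.49, mostly dim in the clones) lists lay the opposite way. The chromatin (-0.08), replication (-0.04), mitosis (-0.02) and hypoxia (0.02) lists did so by less. A difference between clones, as in where the vectors inserted, a difference in the state of that culture at harvest or a shift of those gene groups alone, may each account for it and stay open, since each clone is 1 array.

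The 5' signal of the actin control, which the annotation assigns to ACTG1, was lower in iPPSC while the 3' signal was not, a 3.54-fold difference in their ratio. RNA degradation or short cDNA could raise the ratio of other controls as well. That of GAPDH was 1.00 times and that of EF1-alpha 1.13 times the PFF value. In both groups the 5' signal of EF1-alpha was the higher, with ratios of 0.87 in iPPSC and 0.77 in PFF. Transcript lengths were not compared, so a shortening that affects actin more than these controls is not excluded. Saturation of the bright 3' probe set could hide a fall, and cannot be told apart from a difference between transcript ends, because 3 dimmer ACTG1 probe sets went both ways (median -0.35). Binding of transcripts from other actin genes, and a difference in actin expression between the cell states, were not tested.

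KLF4 and MYC signals were lower in iPPSC although human KLF4 and c-MYC had been introduced, and all 32 genes of ribosome biogenesis and MYC targets rose. The probe sets may report only the pig's own genes, which the difference of MYC (-4.54) cannot settle without probe sequences. Loss of serum stimulation could lower both. The 17 measured immediate-early genes had a median of -1.75, of which 14 fell and 0 rose. Those that did not pass were FOS (-0.60), EGR1 (-0.26) and IER2 (0.52). Some that fell, such as CCL2 and VEGFA, also belong to the mesenchymal and hypoxia lists. Because the culture medium differed with the group, loss of serum stimulation cannot be told apart from a difference between the cell states.

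An extra or missing chromosome in a clone, a hypothesis raised for cultured stem cells, was tested by the median difference of each clone from the others over the genes of each chromosome, grouped by the reference table. Over 19 chromosomes with at least 81 genes each, the largest median had a size of 0.052, against 0.585 for an extra copy in all cells with a proportional effect on expression. The 0.585 holds for log2 signal without the added 16. Dim genes would lower it on the log2(signal + 16) scale, by an amount that was not computed. A gain in a small share of cells, and one shared by all clones, remain untested.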
